A study of Mus musculus with 31 samples.

How the data were processed

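The series holds RNA sequencing of mouse embryonic brain in 4 groups. Dorsal and ventral diencephalon of wild-type embryos at embryonic day (E) 10.5 were sequenced in bulk, with 3 libraries per region. Smart-seq2, a full-length RNA-seq method for very small inputs, was run on 13 libraries labelled Axin2-null and 12 libraries labelled Axin2 wild type, made at E11.5 from the medial cortex of Emx1-CreERT2::MADM-11::Axin2LacZ embryos. MADM (mosaic analysis with double markers) recombines a chromosome pair so that mutant and wild-type sister cells carry different fluorescent colours, here on chromosome 11, which holds Axin2. Groups were taken from the labels. The columns of the Smart-seq2 table named a genotype by colour letter but could not be tied to a numbered sample, so each was used as a library of its genotype without a number of its own. All columns of both tables belonged to a group.

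Per the submitters' processing notes, STAR 2.7.0a, Trimmomatic and featureCounts were used with the mouse builds mm10 and GRCm38; the notes give these names without a role or an order. The deposited bulk table is named as TPM, but its columns sum to between 17604411 and 20838226, and 46.6% of its values above 0 were whole within 0.0001, so the values were treated as estimated counts as the authors deposited them. The deposited Smart-seq2 table holds TPM (transcripts per 1000000), since its columns sum to between 999999.57 and 1000000.7; TPM keeps no depth, so the depth of these libraries is unknown. In GENCODE M21, 34581 of the 34865 bulk identifiers and 55141 of the 55487 Smart-seq2 identifiers had a symbol. Coordinates are those of GENCODE M21 on GRCm38.

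The test planned before the data were examined was limma on log2(TPM + 1) for the bulk table. Because the table holds estimated counts, these were rounded to whole numbers and tested with edgeR 4.0.16 (TMM scaling, estimated dispersions, quasi-likelihood fit and F test) in R 4.3.3. Genes with a mean of at least 1 CPM (counts per 1000000 counts) over the 6 libraries were tested, the CPM minimum taking the place of the planned TPM minimum, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values are given as mean ± SD over 3 libraries after TMM scaling. A fold against a region with no counts is a lower bound computed against 3 counts over the region. Nothing in the labels says that the 3 libraries of a region came from separate embryos, so the p-values measure the spread between these libraries, which may be technical. Replicates were compared by a chi-square statistic per gene. It was 8.5 between dorsal libraries 1 and 2, 19.6 between ventral libraries 1 and 2 and at least 70.0 for the other within-region pairs. No pair agreed within sampling noise, and each library was counted. Separate libraries of 1 RNA can also differ by more than sampling noise, so this does not show that the libraries were independent. Libraries 1 and 2 were the closest pair in each region (correlations 0.9948 in dorsal and 0.9871 in ventral). If they shared a source, the p-values are too small. Gene lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), again with an estimated correlation, and with fry of the same package. Unlike camera, fry does not compare a list with the other genes.

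In the Smart-seq2 table the labels call each sample a single cell and name no animal, so each genotype counts as 1 sample here, although more than 1 embryo contributed. If a library held several cells, the SDs and shares describe pools. No test between genotypes was made and no number of changed genes is given. Means and SDs over libraries describe these libraries only. For 13680 genes with a mean of at least 1 TPM over the 25 libraries, the difference of mean log2(TPM + 1) between null and wild type was computed. The median difference of each list is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 classes, as a description and not a p-value. A gene counted as detected at 1 TPM or more. Shares of libraries carry exact 95% binomial (Clopper-Pearson) intervals, which cover counting error only.

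The genes named in the text follow a rule fixed in advance. In bulk they are Axin2, then the 10 genes with the largest log2 fold change per direction among those past the threshold, with at least 10 CPM in the higher region and no overlap between regions, then up to 2 members past the threshold per direction of each of 39 fixed gene lists, or the 2 members with the highest means where none passed. In the Smart-seq2 libraries they are Axin2, the 10 genes with the largest difference per direction among genes detected in at least 50% of the libraries of the higher genotype, and up to 2 members per direction of each list. Predicted and clone-named genes were left out, and some genes that the rule names are not reported here. Other genes are named as chosen after their values were seen. Lists of adult organ genes, hypothalamic neuropeptides and cortical neuron factors were written after some of their members' values had been seen.

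The bulk test was tested on simulated counts for the same 14701 genes with 200 changed genes. It recovered 2% of genes changed 1.5-fold, 24% of those changed 2-fold, 80% of those changed 4-fold and 78% of those changed 8-fold, with 0 false calls. The simulated libraries held no differences shared between genes, and 200 genes were changed where 2453 were called in the data. These rates therefore do not carry over to the real libraries. In a simulated Smart-seq2 comparison of 13680 genes a list shifted by 1 on the log2 scale was found at 0.89, at percentile 100.0. Of 33 unshifted lists, 2 lay outside the central 95% of random lists. The simulated genes varied independently, so this share does not apply to lists whose genes vary together. A simulated trend with exonic length over 11856 genes was found within 0.109 on the log2 scale. Alternatives changed the filter, the scaling, the test, the pseudocount, the detection limit and the libraries. The additions made after the data were seen were limma on log2(CPM + 1), DESeq2 1.42.0, total-count scaling, a minimum of 0.5 CPM in both regions, length-matched random lists and 3 subsets of the Smart-seq2 libraries. Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6 was used for the rest.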

Results

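Bulk RNA-seq measured gene expression in 3 dorsal and 3 ventral diencephalon libraries of wild-type mouse embryos at E10.5. The dorsal libraries held 20622702, 20549847 and 17604166 counts, and the ventral libraries 20838002, 19095390 and 17769770. Smart-seq2 profiles of the E11.5 medial cortex comprised 13 libraries labelled Axin2-null and 12 labelled Axin2 wild type. The title of the study concerns Axin2, a negative-feedback gene of the Wnt pathway, in competition between stem cells of the developing brain.

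The comparison of dorsal with ventral diencephalon addresses how Axin2 and the rest of the transcriptome differ between these regions. Axin2 (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783, plus strand) was at 13.2 ± 5.22 CPM in dorsal and 3.12 ± 1.14 CPM in ventral libraries (SD, n = 3 each), 4.22-fold higher in dorsal. Its log2 fold change was 2.08 with a standard error of 0.45 and an adjusted p of 0.0175 (edgeR quasi-likelihood test), and all 3 dorsal libraries lay above all 3 ventral ones. Dorsal libraries were also rich in the forebrain transcription factor Tbr1 at 424 ± 72.2 CPM against 3.01 ± 1.58 CPM. Whether they held telencephalic tissue was not tested, so the Axin2 difference cannot be assigned to the diencephalon alone. Ventral libraries were rich in the hypothalamic transcription factor Nr5a1 at 162 ± 42.8 CPM against 0.840 ± 0.493 CPM in dorsal. The Axin2 call was lost without dorsal library 1 (log2 fold change 2.13, adjusted p = 0.0635), without ventral library 1 (1.99, adjusted p = 0.0765) and without ventral library 2 (1.88, adjusted p = 0.0661), while its adjusted p ranged from 0.000209 to 0.0765 over all alternatives.

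Of 14701 genes tested, 1050 were higher in dorsal and 1403 higher in ventral diencephalon, and 791 and 1195 of these by more than 2-fold. Without ventral library 3 the count higher in dorsal was 1695, and it fell to 498 without dorsal library 1, 561 without dorsal library 2, 530 without ventral library 1 and 600 without ventral library 2. The count higher in ventral was 843, 909, 920 and 900 without those same 4 libraries in that order. Among the calls higher in ventral, 557 had a dorsal mean under 0.5 CPM, and 54 calls higher in dorsal had a ventral mean under 0.5 CPM. Over the 13859 genes with at least 0.5 CPM in both regions, a setting chosen after seeing the data, 872 were higher in dorsal and 752 in ventral. Ventral library 3 correlated at 0.9253 and 0.9141 with ventral libraries 1 and 2, which correlated with each other at 0.9871 across genes.

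**Figure D1:**
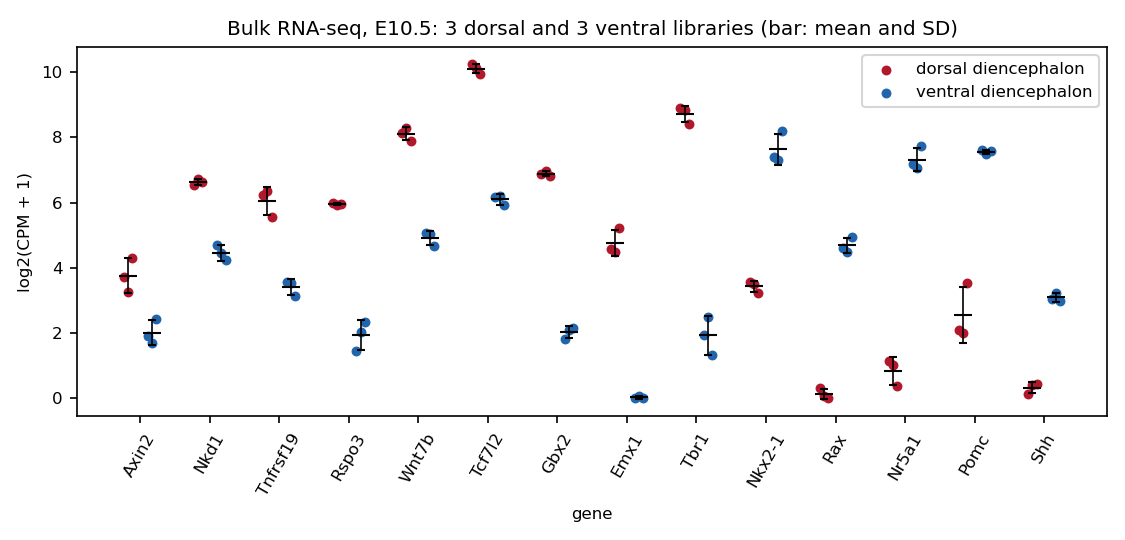
Expression as log2(CPM + 1) of 14 genes in 3 dorsal (red) and 3 ventral (blue) libraries, with points for libraries and bars for mean and SD. Axin2 was at 13.2 CPM in dorsal and 3.12 CPM in ventral on average, and Nr5a1 at 0.840 and 162 CPM.

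The 10 genes highest in dorsal by fold change included several transcription factors. Emx1, a cortical homeobox gene (chromosome 6, 85187438 to 85204462), was at 26.9 ± 8.06 CPM in dorsal and had 1 count over the 3 ventral libraries. Dmrt3 (chromosome 19, 25610301 to 25623921) was at 37.4 ± 3.67 CPM with 3 counts over ventral. Slc17a7, which encodes a vesicular glutamate transporter, was 426-fold higher at 77.9 ± 17.2 CPM. Tfap2d was 204-fold higher, Trp73, a gene of the p53 family, 143-fold, Tbr1 141-fold and the hedgehog effector Gli2 125-fold. The other 3 were Vcp-rs, a Vcp-related sequence on chromosome X for which reads shared with Vcp were not excluded, at 111-fold, Tiam2 at 97.7-fold and Gas1 at 69.2-fold.

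The 10 genes highest in ventral by fold change included defensin, immunoglobulin and amylase genes. Defa2, an antimicrobial peptide of Paneth cells, was at 19.6 ± 8.27 CPM in ventral with no counts in dorsal, at least 389-fold higher. Also without dorsal counts were the immunoglobulin genes Iglv1 (at least 352-fold higher) and Igkv10-96 (at least 235-fold), the antigen-presentation gene H2-Aa (at least 282-fold), Fbp2 (at least 215-fold) and Gstm3 (at least 213-fold). Amy2a1, a pancreatic amylase, reached 88.5 ± 82.97 CPM, and the defensins Defa23 and Defa3 reached 206 ± 113 and 81.0 ± 46.6 CPM. Aadac stood at 21.4 ± 16.5 CPM. Defensin and amylase genes are near-identical families, so reads could be split among members.

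Lists of adult organ genes, written after those top genes were seen, gave the extent of this signal. Of 33 tested small-intestine genes, 32 were higher in ventral, as were all 14 tested exocrine pancreas genes and 6 of 7 genes of B and plasma cells. Small-intestine genes took 0.802%, 1.39% and 0.410% of the counts of ventral libraries 1, 2 and 3 and between 0.00315% and 0.00352% of the dorsal libraries. Pancreas genes took 0.221%, 0.403% and 0.0962% of the ventral libraries. Reg3b, an intestinal lectin, was at 1759 ± 1077 CPM in ventral and 2.84 ± 0.335 CPM in dorsal. The only tested lung gene and the only tested kidney gene did not pass the threshold and no testis gene reached the minimum for testing, while 1 of 2 tested liver genes (Cyp3a11) and the only tested muscle gene (Acta1) were higher in ventral.

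**Figure D2:**
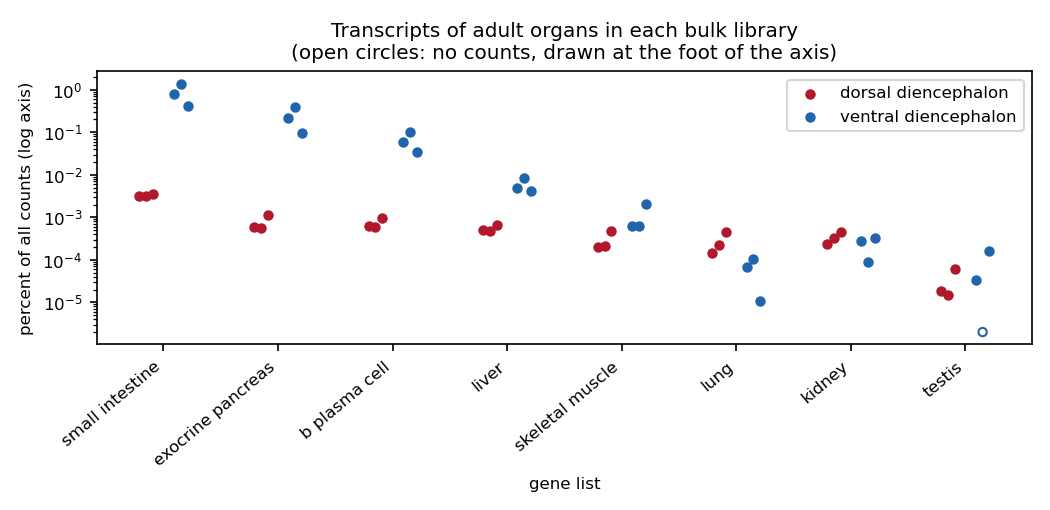
Share of all counts in each bulk library, as a percent on a log axis, taken by 8 lists of adult organ genes, with red points for dorsal and blue for ventral libraries. Small-intestine genes took 0.802%, 1.39% and 0.410% of the ventral libraries; an open circle marks a library with no counts for the list.

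Regional identity genes split by region. In the list of thalamic, epithalamic and pretectal genes, 20 of 22 tested members were higher in dorsal and 1 in ventral (20 and 2 adjusted over the list alone). Tal1 had no ventral counts and was at least 95.2-fold higher in dorsal, Irx1 was at 4.89 ± 2.47 against 0.0707 ± 0.0834 CPM, and Dbx1 was higher in ventral at 42.2 ± 4.10 against 14.8 ± 1.93 CPM. Of 29 tested hypothalamic genes, 20 were higher in ventral and 5 in dorsal (20 and 5 adjusted over the list alone), with Rax, a hypothalamic and retinal homeobox gene, at 24.98 ± 4.37 against 0.0945 ± 0.124 CPM. Fezf2 and Sp9 of that list were higher in dorsal, at 129 ± 4.64 against 26.8 ± 6.17 CPM and 86.4 ± 12.3 against 18.5 ± 12.4 CPM. The thalamic call held with an estimated correlation (adjusted p = 0.00367), and the hypothalamic call was lost (adjusted p = 0.108 with an estimated correlation). By fry both lists passed (adjusted p = 1.21e-06 and 0.0017). Of 17 tested cortical identity genes, 13 were higher in dorsal and 0 in ventral (16 and 0 adjusted over the list alone, adjusted p = 0.00367 with an estimated correlation).

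Among Wnt pathway genes past the threshold, more were higher in dorsal than in ventral. Of 15 tested feedback and target genes, 4 were higher in dorsal and 1 in ventral (5 and 1 adjusted over the list alone). Besides Axin2, Tnfrsf19 was at 67.1 ± 18.8 against 9.73 ± 1.77 CPM and Sp8 at 9.45 ± 2.35 against 1.82 ± 0.594 CPM, while Dkk1, a secreted Wnt inhibitor, was higher in ventral at 11.8 ± 6.82 against 2.12 ± 0.871 CPM. The list of ligands and R-spondins also holds Wls and Porcn. Of its 12 tested genes, 5 were higher in dorsal and 0 in ventral (5 and 0 adjusted over the list alone). Among them were Rspo3 at 61.1 ± 1.76 against 2.96 ± 1.18 CPM and Rspo2 at 4.29 ± 1.06 against 0.214 ± 0.289 CPM. The list of receptors and destruction complex genes also holds the transcription factors Tcf7l1 and Tcf7l2. Of its 21 tested genes, 6 were higher in dorsal and 1 in ventral (10 and 1 adjusted over the list alone). Fzd10 was at 5.67 ± 3.08 against 0.0526 ± 0.0543 CPM. Tcf7l2, also in the thalamic list, was at 1108 ± 111 against 67.7 ± 7.31 CPM. Fzd5 was higher in ventral at 13.4 ± 2.39 against 0.293 ± 0.216 CPM. The camera calls of all 3 Wnt lists were lost with an estimated correlation (adjusted p = 0.108, 0.137 and 0.235). All 3 passed by fry (adjusted p = 0.000464, 0.00261 and 0.00731). The estimated correlations were -0.041, 0.18 and 0.21. That of the feedback list lay below the preset 0.01, so a higher correlation does not account for its lost call. Of 13 roof plate and dorsal genes, 8 were higher in dorsal and 0 in ventral (10 and 0 adjusted over the list alone, adjusted p = 0.0346 with an estimated correlation), including Zic2 at 4.13 ± 0.627 against 0.103 ± 0.0991 CPM. Of 13 floor plate and hedgehog genes, 6 were higher in dorsal and 1 in ventral (6 and 3 adjusted over the list alone), with Shh itself higher in ventral at 7.54 ± 0.808 against 0.257 ± 0.141 CPM and Gas1 and Gli2 higher in dorsal (adjusted p = 0.0680 with an estimated correlation).

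Cell cycle genes were higher in dorsal. Of 33 tested S phase genes, 21 were higher in dorsal and 0 in ventral (27 and 0 adjusted over the list alone), with Rrm2 at 244 ± 63.0 against 43.7 ± 12.6 CPM and Uhrf1 at 76.4 ± 14.9 against 13.8 ± 0.265 CPM. Of 33 G2 and M phase genes, 28 were higher in dorsal and 0 in ventral (31 and 0 adjusted over the list alone), such as Kif11 at 78.2 ± 15.6 against 10.8 ± 8.70 CPM and Cenpe at 56.2 ± 4.86 against 9.43 ± 5.73 CPM. Both calls held with an estimated correlation (adjusted p = 0.0160 and 0.0447). Of 19 neural progenitor genes, 5 were higher in dorsal and 2 in ventral (7 and 3 adjusted over the list alone), with Pax6 and Nes higher in dorsal and Sox1 and Sox3 higher in ventral (adjusted p = 0.108 with an estimated correlation). Of 34 neuron genes, 14 were higher in dorsal and 4 in ventral (18 and 6 adjusted over the list alone, adjusted p = 0.0102 with an estimated correlation), with Gap43 and Lhx5 among those higher in ventral. Of 14 Notch pathway genes, 5 were higher in dorsal and 0 in ventral (5 and 0 adjusted over the list alone), including Hey1 at 38.9 ± 10.02 against 8.49 ± 1.27 CPM and Lfng (adjusted p = 0.238 with an estimated correlation).

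Of 34 tested p53 pathway genes, 5 were higher in dorsal, 1 was higher in ventral and 28 did not pass the threshold, with the same 5 and 1 counted when adjusted over the list alone; the list as a whole did not pass (adjusted p = 0.0763). Psrc1 was at 29.3 ± 10.6 against 6.33 ± 3.49 CPM and Pidd1 at 20.4 ± 2.999 against 5.15 ± 1.34 CPM, while Perp was higher in ventral at 16.1 ± 4.55 against 1.53 ± 0.641 CPM. Of 25 genes linked to cell competition, 3 were higher in dorsal and 2 in ventral (4 and 2 adjusted over the list alone), with Yap1 and Llgl1 higher in dorsal and Sparc and Ccn2 higher in ventral, and the list did not pass (adjusted p = 0.549). Of 18 apoptosis genes, 2 were higher in dorsal, Birc5 and Parp1, and 0 in ventral (2 and 0 adjusted over the list alone), and the list did not pass (adjusted p = 0.289). Of 30 ribosomal protein genes 0 passed the threshold by edgeR and 0 by DESeq2, and 1 had an unadjusted p under 0.05.

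Of 7 lists for other cell types and states that passed, only the immediate early and imprinted lists kept their call with an estimated correlation. Of 8 tested epithelial and pituitary genes, 5 were higher in ventral and 0 in dorsal (6 and 1 adjusted over the list alone), with Krt8 at 36.4 ± 13.4 against 0.178 ± 0.171 CPM and Krt19 at 29.6 ± 20.9 against 0.180 ± 0.190 CPM (adjusted p = 0.235 with an estimated correlation). Of 6 macrophage genes, 3 were higher in ventral and 0 in dorsal (4 and 0 adjusted over the list alone), including Lyz2 and Ctss (adjusted p = 0.291 with an estimated correlation). These same ventral libraries carried the intestinal and pancreatic transcripts given above. Of 7 red blood cell genes, 2 were higher in dorsal and 0 in ventral (2 and 0 adjusted over the list alone), the embryonic globins Hbb-y at 31.5 ± 18.3 against 1.23 ± 0.528 CPM and Hba-x, which had no ventral counts and was at least 81.4-fold higher (adjusted p = 0.269 with an estimated correlation). Of 18 immediate early genes, 7 were higher in ventral and 0 in dorsal (8 and 0 adjusted over the list alone, adjusted p = 0.0447 with an estimated correlation), among them Egr2 and Egr3. Of 13 mitochondrially encoded genes, 5 were higher in ventral and 0 in dorsal (12 and 0 adjusted over the list alone), and mitochondrial counts made up 1.58%, 1.56% and 1.14% of the dorsal and 2.76%, 3.74% and 1.73% of the ventral libraries (adjusted p = 0.394 with an estimated correlation). Of 16 imprinted genes outside chromosome 11, 11 were higher in ventral and 0 in dorsal (11 and 0 adjusted over the list alone, adjusted p = 0.0173 with an estimated correlation), with Dlk1 at 672 ± 162 against 50.03 ± 1.501 CPM. Of 17 heat shock and unfolded protein response genes, 4 were higher in ventral and 0 in dorsal (5 and 0 adjusted over the list alone, adjusted p = 0.259 with an estimated correlation), including Chac1 and Asns. Lars2 took 2.44% of the counts of dorsal library 3 and between 0.0295% and 0.277% of the others.

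Further lists held genes past the threshold in both directions or few of them. Of 14 cortical hem genes, 8 were higher in dorsal and 1, Id3, in ventral (10 and 2 adjusted over the list alone, adjusted p = 0.0680 with an estimated correlation). Of 15 ventral telencephalic genes, 3 were higher in dorsal, among them Gsx2 and Sp9, and 4 in ventral, among them Nkx2-1 and Gsx1 (4 and 5 adjusted over the list alone), and the list did not pass (adjusted p = 0.0973). Of 8 optic vesicle and retina genes, 1 was higher in dorsal and 3 in ventral (2 and 3 adjusted over the list alone, adjusted p = 0.220 with an estimated correlation), and the list's median log2 fold change of 0.16 differed in sign from its mean of -1.64. Of 3 hindbrain and spinal cord genes, Gbx2 was higher in dorsal and Egr2 in ventral (1 and 1 adjusted over the list alone, adjusted p = 0.213 with an estimated correlation). Of 3 midbrain genes, Nr4a2 and Otx2 were higher in dorsal and Th in ventral (2 and 1 adjusted over the list alone). Of 11 BMP response genes, Smad6 and Id2 were higher in dorsal and Id3 in ventral (3 and 1 adjusted over the list alone), and of 13 FGF genes, Fgf15 and Etv1 were higher in dorsal (2 and 0 adjusted over the list alone). Of 24 ribosome biogenesis genes, Utp20 and Fbl were higher in dorsal, and 0 passed when adjusted over the list alone. In each case 1 gene was higher in ventral among 10 mesenchyme genes (Foxd1), 7 endothelial genes (Sox18) and 23 nuclear oxidative phosphorylation genes (Uqcrfs1), with 2, 1 and 0 when adjusted over the list alone. Of 7 neural crest genes, 1 was higher in dorsal, Tfap2b, and 1 in ventral (1 and 1 adjusted over the list alone), and of 5 imprinted genes on chromosome 11, Cobl and Ddc were higher in ventral (2 adjusted over the list alone). The midbrain, BMP, FGF, ribosome biogenesis, mesenchyme, endothelial, oxidative phosphorylation, neural crest and chromosome 11 imprinted lists did not pass as lists (adjusted p from 0.0990 to 0.938). By edgeR 0 of 20 hypoxia and glycolysis genes passed, where 3 higher in dorsal and 2 higher in ventral had an unadjusted p under 0.05 and DESeq2 called 2 and 2. Of 4 sex-linked genes 0 passed by edgeR or DESeq2 and 0 had an unadjusted p under 0.05.

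**Figure D3:**
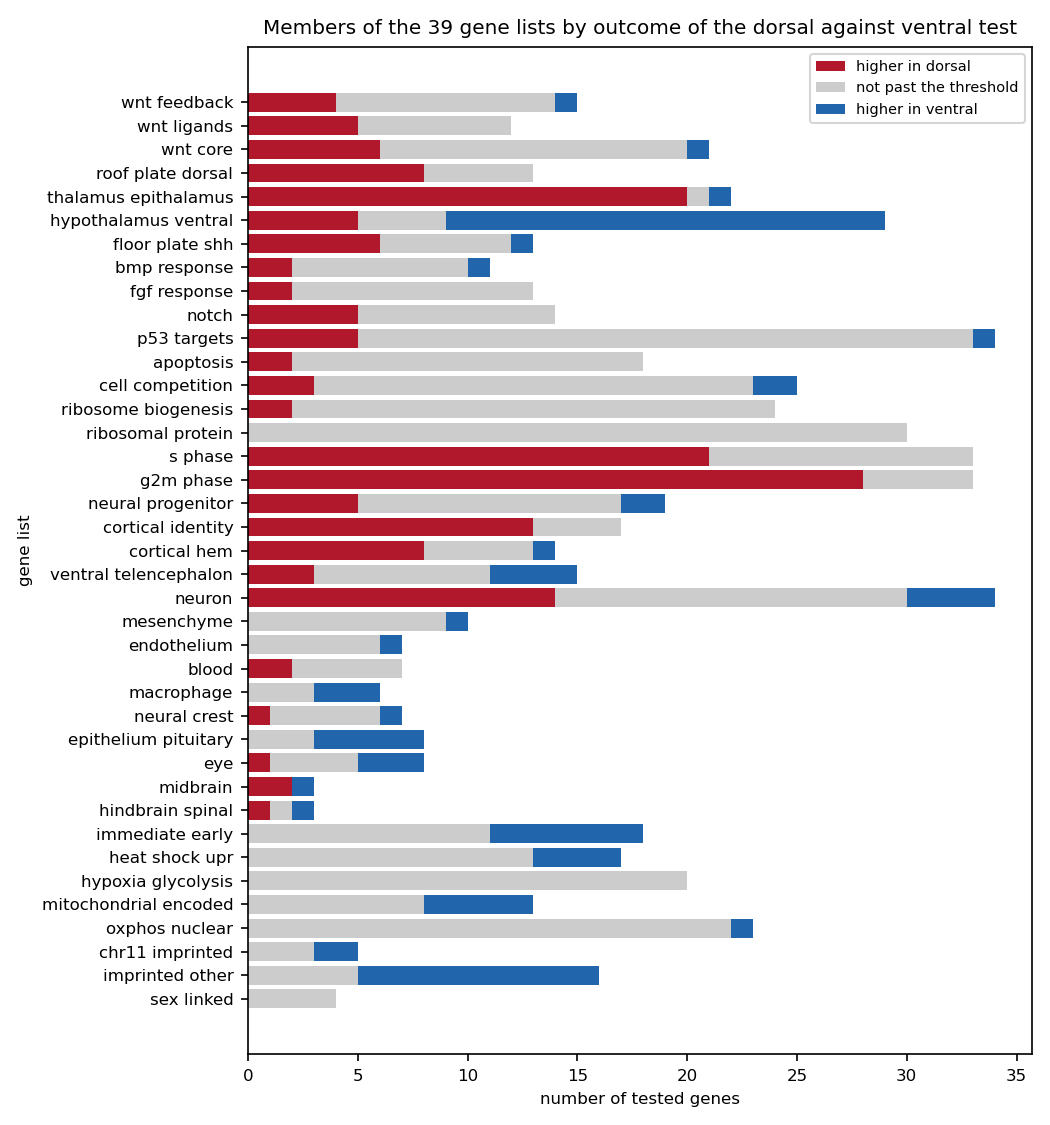
Number of tested genes in each of 39 gene lists that were higher in dorsal (red), not past the threshold (grey) or higher in ventral (blue) diencephalon. Of 22 thalamic and epithalamic genes 20 were higher in dorsal, and of 29 hypothalamic genes 20 were higher in ventral.

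The Smart-seq2 libraries address how loss of Axin2 changes cells of the E11.5 medial cortex. Axin2 averaged 6.17 TPM (SD 6.996) over the 13 libraries labelled Axin2-null and 13.8 TPM (SD 8.79) over the 12 labelled wild type, a difference of -1.37 in mean log2(TPM + 1). It ranged from 0 to 22.4 TPM in the null and from 4.32 to 35.9 TPM in the wild-type libraries, and 3 null libraries lay above the wild-type mean. Axin2 was detected in 11 of 13 null libraries (84.6%, exact 95% interval 54.6 to 98.1%) and in all 12 wild-type libraries (100%, 73.5 to 100%), and at 10 TPM or more in 3 and 8 of them. The part of Axin2 that the LacZ allele replaces is not given in the sources used here, so residual Axin2 signal does not check the labels, and every direction below rests on the libraries as labelled. With a pseudocount of 0.1 the difference was -1.82, and with a pseudocount of 10 it was -0.58. Leaving out 1 library at a time moved the difference between -1.56 and -1.18. Subsets by sex-linked RNA, chosen after the data were seen, were split at 5 TPM. Here and below, "only" means that the other RNA was under 5 TPM, not absent. The difference was -1.38 in libraries with only Y-linked RNA (7 null, 4 wild type) and -1.27 in those with only Xist RNA (4 null, 6 wild type). It was -1.93 in those with both (1 null, 2 wild type). A null library with only Y-linked RNA held Xist at 4.86 TPM, and wild-type libraries with only Xist RNA held Y-linked RNA at up to 2.22 TPM. Embryos of both sexes thus contributed to both genotypes, but the labels tie no library to an embryo and no test between genotypes was made.

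**Figure D4:**
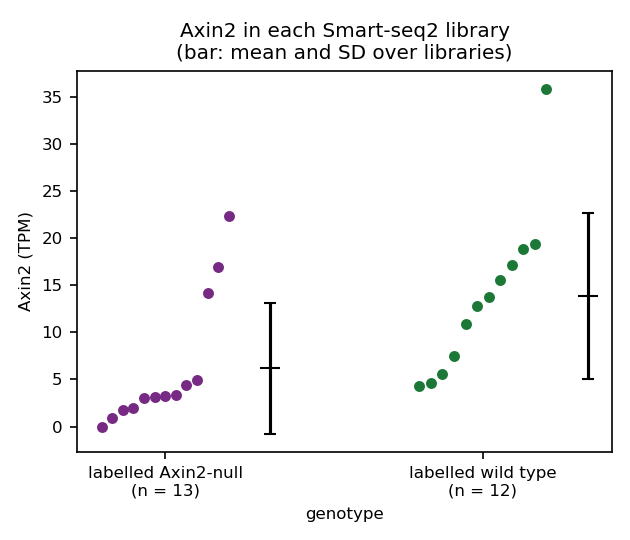
Axin2 in TPM in each of 13 Smart-seq2 libraries labelled Axin2-null and 12 labelled wild type, with bars for mean and SD over libraries. The means were 6.17 and 13.8 TPM, and 3 null libraries lay above the wild-type mean.

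Across the 13680 genes the median difference between null and wild type was -0.22 on the log2 scale, so lower values in the null libraries are set against random lists below. The libraries held between 7863 and 12209 detected genes, with medians of 10791 for null and 11271 for wild type, and 3580 genes were detected in all 25. Both Xist and Y-linked RNA reached 5 TPM in 3 libraries, and whether each library held RNA of 1 cell or of several was not tested. The ribosomal RNA-like gene CT010467.1 took between 1.05% and 32.7% of TPM and exceeded 15% in 5 libraries, which included the 3 with both Xist and Y-linked RNA.

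Among single genes, the largest differences toward null were Psmb10, an immunoproteasome subunit, at 49.1 against 17.5 TPM, and the histone gene Hist1h2bb at 29.4 against 0.618 TPM, where the SD over null libraries was 68.8 TPM. Mutyh, a DNA glycosylase, averaged 22.6 against 9.54 TPM and Mt3, a metallothionein, 60.7 against 23.1 TPM. The other 6 were Izumo4, Ctsk, Hist1h2bj, Hist1h4m, Dus4l and Gpank1, with differences from 1.68 to 1.88. Toward wild type, Edil3 averaged 18.8 TPM against 3.64 TPM in null, and Ndc80, a kinetochore gene, 42.9 against 19.4 TPM. Efcab7, Lpcat4, Morc2a, Insl6, Syap1, Lysmd2, Trim33 and Exoc6b had differences between -2.39 and -2.17. Histone genes are near-identical copies, so reads could be split among them.

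Of 16 measured Wnt feedback genes, 15 were lower in the null libraries, with a median difference of -0.42 at percentile 17.7 of random lists. Leaving out 1 library moved that median between -0.57 and -0.28 and its percentile between 7.35 and 56.1, and the percentile was 69.95 in the libraries with only Y-linked RNA. Tnfrsf19 averaged 68.2 against 102 TPM, while Nkd2 averaged 5.18 against 4.79 TPM. All 12 measured genes of the Wnt ligand list, which also holds R-spondins, Wls and Porcn, were lower in null. Their median was -0.62 at percentile 3.90, and at 0.600 to 18.8 without 1 library. Wls, needed for Wnt secretion, was at 27.4 against 61.3 TPM. The cortical hem list, which shares Wnt and BMP genes with those lists, had a median of -0.65 at percentile 0.860, and at up to 7.58 without 1 library. Its low place also depended on the scale of the values. The percentile was 5.275 with a pseudocount of 0.1, 3.19 with a pseudocount of 10 and 6.15 with log2 of mean TPM + 1. These percentiles lay above the lower limit of 2.5 for random lists. Rescaling to nuclear protein-coding genes left the hem list below that limit, at 1.02. The hem list was at percentile 2.94 in the libraries with only Y-linked RNA (median -0.85) but at 52.6 in those with only Xist RNA (median -0.12). Of 14 roof plate genes, 12 were lower (median -0.57, percentile 2.82, but -0.19 and 41.5 in the libraries with only Xist RNA), with Ttr at 485 against 434 TPM as an exception.

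Of 31 measured p53 pathway genes, 12 were higher and 19 lower in null, with a median difference of -0.21 at percentile 69.5. Leaving out 1 library moved the median between -0.29 and -0.06 and the percentile between 46.1 and 93.6, and the libraries with only Y-linked RNA gave -0.48 at percentile 32.4 and those with only Xist RNA 0.20 at percentile 98.9. Dcxr averaged 14.5 against 6.77 TPM and Ercc5 9.53 against 17.3 TPM. Cell competition genes had a median of -0.27 at percentile 43.4, with Wwtr1 at 9.36 against 5.46 TPM and Lats2 at 1.26 against 5.77 TPM. Without 1 library the median was between -0.34 and -0.12 and the percentile between 25.1 and 76.9, and the percentile was 85.45 in the libraries with only Y-linked RNA and 15.4 in those with only Xist RNA. Apoptosis genes had a median of -0.17 at percentile 53.4, with Casp8 at 2.94 against 9.32 TPM, and without 1 library the median was between -0.27 and 0.002 and the percentile between 23.5 and 88.6.

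The 13 mitochondrially encoded genes were all lower in null (median -1.29, percentile 0), with mt-Nd3 at 1001 against 1561 TPM and mt-Atp6 at 953 against 1576 TPM. The size of this difference varied, with medians of -0.54 in the libraries with only Y-linked RNA, where 2 of the 13 genes were higher in null, -2.21 in those with only Xist RNA and -0.78 with log2 of mean TPM + 1. In 1 null library, which is 1 of the 4 null libraries with only Xist RNA, the mean log2(TPM + 1) of the list was 3.92, where the other 24 libraries lay between 8.19 and 11.7. Of 8 red blood cell genes, 7 were higher in null (median 0.49, percentile 100), and without 1 library the median was between 0.26 and 0.68 and the percentile between 91.3 and 100, with Hba-a1 at 4665 against 2571 TPM. For Hbb-bh1 the mean TPM was higher in null, at 139 against 111, but its mean log2(TPM + 1) was lower in null (difference -0.42). Of 30 ribosomal protein genes, 29 were higher (median 0.25, percentile 94.3). S phase genes had a median of -0.26 at percentile 4.52, but the direction depended on the libraries, with -0.62 at percentile 0.200 in those with only Y-linked RNA and 0.05 at percentile 51.4, with 19 of 33 genes higher in null, in those with only Xist RNA. Neural progenitor genes lay at percentile 4.51, and at 64.6 and 35.8 in these subsets, with Prom1 at 40.7 against 75.9 TPM and Fabp7 at 1520 against 1216 TPM. Of the imprinted genes on chromosome 11, Grb10 averaged 51.8 against 80.9 TPM, Commd1 285 against 243 TPM, and Ddc was listed at 0 in every wild-type library and detected in 4 null libraries.

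The other measured lists lay inside the central 95% of matched random lists when mean log2(TPM + 1) over all libraries was used. With a pseudocount of 10, ribosome biogenesis, S phase, endothelial, immediate early and heat shock genes lay below it. With log2 of mean TPM + 1, floor plate, S phase, endothelial, macrophage and immediate early genes did, and with a pseudocount of 0.1 roof plate and heat shock genes. Heat shock genes had a median of -0.30 at percentile 3.51, with Hspb1 at 10.1 against 2.27 TPM and Herpud1 at 17.8 against 33.9 TPM, and without 1 library the median was between -0.56 and -0.23 and the percentile between 0.1 and 10.035. All 16 measured immediate early genes were lower in null (median -0.47, percentile 9.21), but without the 5 libraries above 15% CT010467.1 the median was -0.20 at percentile 80.15 and 3 were higher. In the 3 wild-type libraries above 15% the mean log2(TPM + 1) of this list was between 4.34 and 5.60, and in the other 9 between 2.33 and 3.55. Of 12 FGF genes, 11 were lower (median -0.59, percentile 8.98, but 0.02 and 83.4 in the libraries with only Xist RNA), with Dusp6 at 18.7 against 41.0 TPM. Cortical identity genes lay at percentile 29.3 (median -0.32), neuron genes at 42.2 (median -0.28) and G2 and M phase genes at 19.1 (median -0.15). The Wnt receptor and destruction complex list had a median of -0.33 at percentile 29.1, with its transcription factor Tcf7l2 at 56.8 against 33.8 TPM. Notch genes had a median of -0.09 at percentile 79.3, and endothelial genes -0.54 at percentile 11.8. Thalamic genes lay at percentile 82.8 (median -0.02), hypothalamic genes at 47.8 (median -0.29), floor plate genes at 7.54 (median -0.74) and BMP response genes at 35.9 (median -0.26). Ribosome biogenesis genes lay at percentile 7.76 (median -0.33), nuclear oxidative phosphorylation genes at 81.0 (median 0.20) and hypoxia genes at 25.3 (median -0.14). Mesenchyme, macrophage and neural crest genes lay at percentiles 10.2, 22.9 and 50.4 (medians -0.47, -0.36 and -0.28), and epithelial and midbrain genes at 71.6 and 58.5 (medians -0.07 and -0.27). The imprinted genes on chromosome 11 lay at percentile 86.9 (median 0.19), the other imprinted genes at 6.41 (median -0.38) and the sex-linked genes at 68.4 (median -0.19). The ventral telencephalic, eye and hindbrain lists had 2, 2 and 1 measured genes and were not placed.

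The place of a list depended on the scale of the values, as given above, and on the libraries used. Leaving out 1 library moved the medians of 25 of the 36 lists by over 1.5 times or changed their sign, and 11 of the 33 lists inside the central 95% left it without some library. For neuron genes the median was between -0.40 and -0.04 and the percentile between 14.2 and 91.6, and for G2 and M phase genes the median was between -0.28 and -0.11 and the percentile between 1.82 and 28.6. For macrophage genes the median was between -0.49 and -0.01 and the percentile between 7.37 and 85.6, where 1 wild-type library had a mean log2(TPM + 1) of 5.04 and the other 24 libraries lay between 0 and 3.32, and for neural crest genes the median was between -0.45 and -0.10 and the percentile between 27.9 and 70.7. The percentiles of the remaining lists ran from 20.4 to 58.5 for Wnt receptor and destruction complex genes, 13.9 to 41.1 for cortical identity genes, 2.39 to 26.4 for FGF genes, 23.9 to 58.7 for BMP genes, 49.9 to 93.0 for Notch genes, 2.26 to 19.4 for ribosome biogenesis genes, 87.7 to 97.53 for ribosomal protein genes and 0.120 to 14.6 for S phase genes. They ran from 1.45 to 34.7 for neural progenitor genes, 0.3 to 7.98 for roof plate genes, 5.70 to 22.4 for floor plate genes, 65.1 to 93.0 for thalamic genes, 33.1 to 61.8 for hypothalamic genes, 28.7 to 74.8 for midbrain genes, 3.23 to 20.9 for mesenchyme genes and 2.52 to 25.7 for endothelial genes, and from 48.8 to 83.6 for epithelial genes, 0.890 to 52.5 for immediate early genes, 3.81 to 51.1 for hypoxia genes, 44.4 to 92.3 for nuclear oxidative phosphorylation genes, 71.6 to 94.3 for chromosome 11 imprinted genes, 1.85 to 25.8 for other imprinted genes and 37.8 to 92.1 for sex-linked genes.

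Of the 3 lists outside the central 95%, only the mitochondrially encoded list stayed outside it without each library in turn. In the libraries with only Y-linked RNA the lists below it were S phase, macrophage (median -1.63, percentile 0.01), heat shock (-0.63, 0.730), hypoxia (-0.50, 2.43) and mitochondrially encoded genes, and those above it were red blood cell and ribosomal protein genes (0.26, 99.5). In the libraries with only Xist RNA the mitochondrially encoded list was below it, the p53 and red blood cell lists were above it, and the medians of 8 lists changed sign. These were the thalamic (0.25), hypothalamic (0.53), FGF (0.02), p53 (0.20), S phase (0.05), macrophage (0.01), epithelial (0.36) and midbrain (0.34) lists, and with only Y-linked RNA the imprinted genes on chromosome 11 changed sign (-0.27). Without the 5 libraries above 15% CT010467.1, the Wnt ligand (-1.07), cortical hem (-0.98), mesenchyme (-0.89, percentile 0.0900), endothelial (-1.01) and mitochondrially encoded lists lay below, and the red blood cell, ribosomal protein and thalamic lists above (0.17 and percentile 98.9 for thalamic genes, whose median changed sign).

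**Figure D5:**
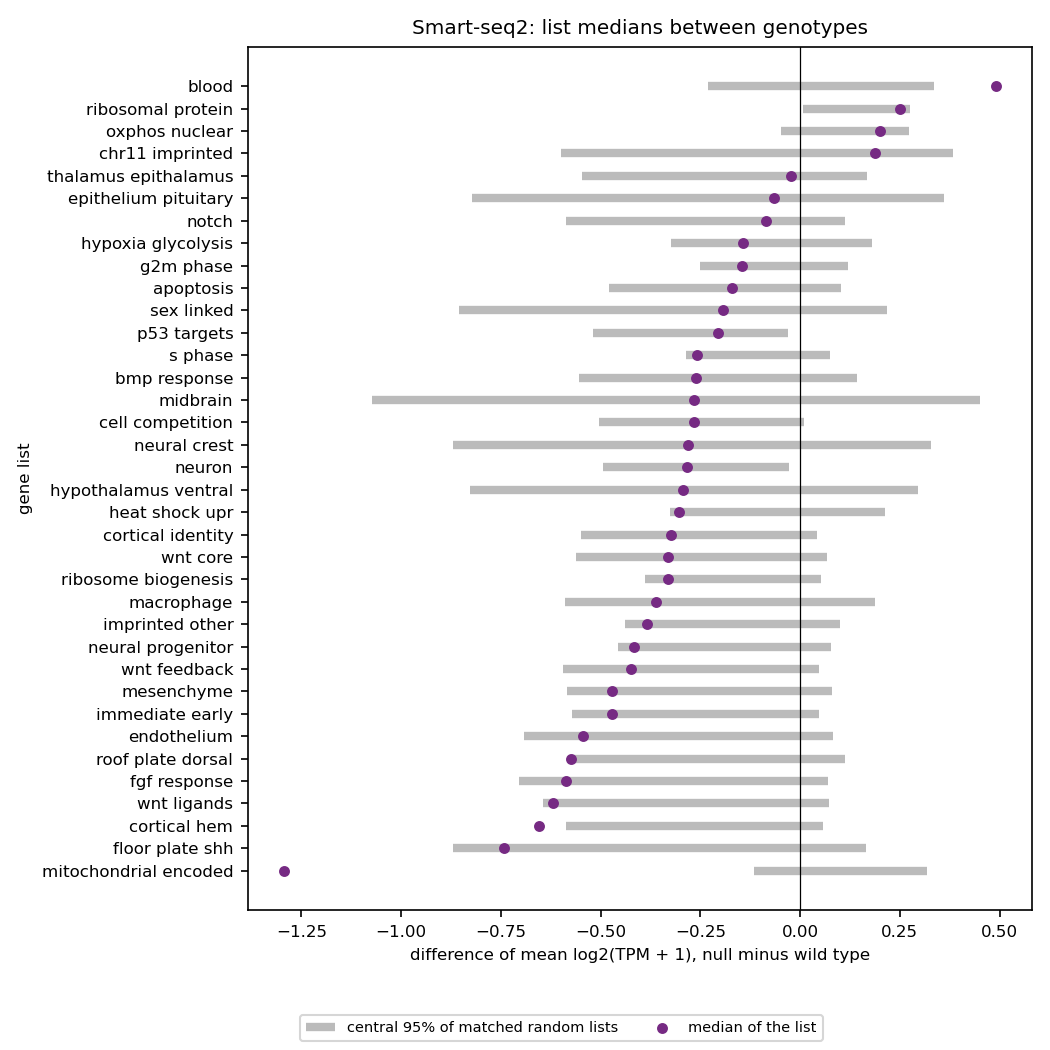
Median difference of mean log2(TPM + 1), null minus wild type, of each gene list (points), with the central 95% of 10000 matched random lists (grey bars). The mitochondrially encoded list lies at -1.29 and the red blood cell list at 0.49.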

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

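The settings marked as added were chosen after the data were seen; the others were planned. No call of a bulk gene or list changed direction under any alternative, and among the 2453 genes called no sign changed.

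The number of genes higher in dorsal (1050) ranged from 498 to 1695 and that higher in ventral (1403) from 843 to 1928 when 1 library was left out, and with at least 0.5 CPM in both regions (added) 752 were higher in ventral. That filter takes out genes nearly absent in 1 region, which include many large changes. The p-values of the genes kept were not recomputed and were only adjusted again, so the further loss of calls comes from that adjustment. Axin2 had a log2 fold change between 1.74 and 2.38 without 1 library and lost its call without dorsal library 1 and ventral libraries 1 and 2. Gene lists higher in dorsal numbered 15 with the preset and 6 with an estimated correlation, and those lower in dorsal 8 and 2; the cause was not tested. With the replicate number as a block, 924 genes were higher in dorsal and 1083 in ventral, 1825 of the 2453 calls were kept, and Axin2 kept its call (adjusted p = 0.0214). The deviations of same-numbered libraries correlated at 0.0992, 0.148 and 0.165, so the numbers were not taken to pair the libraries. DESeq2 (added) called 3551 genes. Of 1787 values for single bulk genes, 1680 stayed on their side of the threshold, 104 lost their call and 3 moved; of 738 values for bulk lists, 36 lost a call, 20 gained one and 20 moved. A Smart-seq2 value is counted as moved when it differs by more than 1 SD over the wild-type libraries: of 1278 values for single genes 65 moved, as did 4 of 337 for lists. That measure leaves out smaller changes of sign. List medians changed sign for 8, 1 and 1 of 36 lists in the Xist-only, Y-only and low-CT010467.1 subsets (all added), 3 with log2 of mean TPM + 1, 2 with a pseudocount of 10 and 0 with a pseudocount of 0.1 or rescaling to nuclear protein-coding genes. The apoptosis, epithelial, Notch, sex-linked and thalamic medians changed sign without some library.

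In the Smart-seq2 libraries the p53 list moved to 0.20 in those with Xist at 5 TPM or more and Y-linked RNA under 5 TPM (added), from -0.21. The number of lists below the central 95% of random lists, 2 in all libraries, was 6 with a pseudocount of 10, 6 with log2 of mean TPM + 1, 5 and 1 in the libraries with only Y-linked or only Xist RNA (added), 5 without the 5 libraries above 15% CT010467.1 (added) and 3 with length-matched lists (added), and ranged from 1 to 7 when 1 library was left out. The number above it, 1 in all libraries, was 2 with only Y-linked, 2 with only Xist RNA, 3 without the 5 libraries and 2 with length-matched lists (all added), and ranged from 0 to 2 when 1 library was left out. The cause was not tested. Axin2 was at 10 TPM or more in 23.1% of null libraries against 84.6% at 1 TPM. No library had fewer than 2000 genes, so leaving out such libraries changed nothing. Depth is unknown for the Smart-seq2 libraries, and 3 bulk libraries per region limit calls of small changes.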

Other observations

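The tests on splits, intestine and pancreas genes, other organ genes and the hypothalamic list were chosen after the result was seen; those on exonic length were set before their values were known.

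Of 14 tested hypothalamic neuropeptide genes, 8 were higher in ventral, 0 in dorsal and 6 did not pass the threshold of the edgeR test. Pomc, the precursor of melanocortins, was at 188 ± 7.92 against 5.63 ± 4.32 CPM, Sst at 150 ± 33.1 against 10.3 ± 5.74 CPM, and Pmch at 91.5 ± 3.4044 against 14.97 ± 2.23 CPM. Of 21 factors and transporters of forebrain glutamatergic neurons, 15 were higher in dorsal, with Neurod6 at 723 ± 121 against 12.6 ± 1.66 CPM, Zbtb18 at 705 ± 134 against 54.1 ± 6.56 CPM and Nfib at 1261 ± 220 against 132 ± 8.06 CPM. Both lists were written after some of these values had been seen.

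The real split of the 6 bulk libraries gave 2453 genes past the threshold, and the highest of the other splits gave 0 genes by edgeR. Among those other splits up to 950 genes had an unadjusted p under 0.05 and up to 93 were called by DESeq2, both in the split of dorsal libraries 1 and 2 with ventral library 3. Of 10 splits 1, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. Each other split also mixed both regions in each group. A regional difference then widens the spread within groups, so the lack of calls there does not measure false calls.

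Digestive-organ transcripts were found in the 3 ventral libraries. A candidate explanation is RNA of adult intestine and pancreas in these libraries. Of 47 tested intestine and pancreas genes, 95.7% were over 10-fold higher in ventral, and 100% lay within 1.5-fold of their median ratio of 1.74 between ventral libraries 2 and 1, where uncalled genes of at least 10 CPM had a median ratio of 0.97. Between ventral libraries 3 and 1 their median ratio was 0.44, and only 33 of the 47 lay within 1.5-fold of it. A general rise of rarely expressed organ genes cannot be told apart. Only 4 lung, kidney, testis, muscle and liver genes reached 1 CPM in ventral, and 25% of these, which is the 1 gene Cyp3a11, were over 10-fold higher. Cyp3a11 of the liver list was 247-fold higher in ventral, and whether its RNA came from liver or intestine was not tested. Acta1 was 9.37-fold and Trf 1.34-fold higher in ventral, and Lrp2 was 1.38-fold higher in dorsal. These 4 genes were picked by their ventral level, so organ genes that stayed low could not count against such a rise. Whether the source was tissue, RNA or reads of another library, or a biological one, was not tested.

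Telencephalic genes lay beside thalamic genes in the libraries labelled dorsal diencephalon. An exchange of dorsal and ventral labels is argued against, since 5 hypothalamic genes past the threshold were higher in dorsal and 20 in ventral. The biological difference between the regions stays open. Whether the stage of the embryos was as labelled was not tested. The neuropeptide and neuron values given above, and haemoglobin at 0.0113% to 0.0303% of the bulk counts, were not compared with a reference for E10.5. They are values of libraries labelled E10.5. Whether the dorsal samples held telencephalic tissue was not tested either. The Axin2, Wnt and cell cycle differences therefore cannot be assigned to the diencephalon alone.

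Most gene lists were lower in the Smart-seq2 libraries labelled Axin2-null. Among 5 classes of exonic length, the longest genes lay below the shortest in each of 4 expression classes, by between -0.52 and -0.218 on the log2 scale, and a loss of long transcripts in the null libraries as the cause cannot be told apart because the smallest gap missed the size set in advance. The Axin2 difference of -1.37 lay at percentile 6.20 of 1000 genes of similar expression and exonic length, whose median was -0.42, so such a loss may account for part of the lower Axin2. The genotype named by the labels stays open as an untested biological explanation. In random lists matched on length as well, the cortical hem list lay at percentile 0.470 and the red blood cell list at 97.8. The roof plate list moved from 2.82 to 1.83 and the ribosomal protein list from 94.3 to 98.0, both then outside the central 95%, and the S phase list from 4.52 to 17.7.

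In the Smart-seq2 libraries, small-intestine genes took at most 0.005% of TPM and B and plasma cell genes at most 0.01%. The lowest values in any of these libraries were 225.5 TPM for the globin gene Hbb-y, 31.8 TPM for the neuronal gene Tubb3 and 7.0 TPM for the cortical gene Emx1.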
